A study of Mus musculus with 2 samples.

How the data were processed

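H3K27me3 ChIP-seq was done on hindbrain from pools of mouse embryos of both sexes at 10.5 days, 1 group with 2 biological replicates (69 and 51 embryos, with 2 and 3 technical replicates, per the labels). Grouping and replicate numbers were taken from the labels. The values used here start from 4 peak lists in narrowPeak format with 10 fields, on mm10 per the labels. Per the file headers and file records, each replicate's list was called on that replicate's alignments with 2 further input files, the same for both replicates; the pooled list was called on the alignments of both; and the replicated list was derived from the pooled list and both replicates' lists. The aligner, the peak caller and its version, the threshold and the rule for calling a peak replicated are not given in the sources used here. The 2 further files are not described in the sources used here.

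The deposited score of a peak (field 5) is a whole number for display, scaled within its list, and was not used. The deposited signal value (field 7) is the authors' enrichment of the peak, whose scale is not stated; it was used to rank and describe peaks, and in the closing section as a ratio between replicates at shared peaks. The deposited −log10 p and −log10 q (fields 8 and 9) are the authors' own; no peak had a −log10 p under 2.00, and they were used for stricter thresholds. The deposited summit offset (field 10) served only to place summits. When tested, every replicated peak was a peak of the pooled list. All 56139 pooled peaks with at least 50% overlap, of either peak, in both replicates were in the replicated list, which held 13550 others as well. Per peak values are the authors' and have no replicate error; where a share or coverage could be computed in each replicate's own list it is given as mean ± SD (n = 2). Read counts are not held in peak lists, so depth is unknown and no counting interval is given.

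Genes, TSSs and transcript features were taken from GENCODE mouse release 21, whose build, GRCm38, is the same as mm10, and all peak ends were checked against its chromosome lengths. The TSS of a gene was the 5' end of its record. A gene was called marked when a replicated peak overlapped the TSS ± 2 kb by at least 1 bp; a wide peak of a neighbour can therefore mark a gene. The tests used protein-coding genes on chromosomes 1 to 19, X and Y (21938 genes). The 19 gene lists (453 genes, none in more than 1 list) and 19 symbol families, the tests, the alternatives and the naming rule were fixed before the data were examined. Lists and families were tested by Fisher's exact test, two-sided, against all other genes, with Benjamini-Hochberg adjustment over the 19 lists or the 19 families, at 0.05. Overlap, annotation and base composition were compared with 100 circular shifts of the peaks along each chromosome, leaving out the leading gap of about 3 Mb (seed 1). Chromosome X was placed by rank among the 19 autosomes. Promoters were called CpG-rich when the observed over expected CpG of the 500 bp either side of the TSS exceeded 0.6. Domains were replicated peaks merged across up to 3 kb.

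Genes named in the text were all Hox genes by cluster; per list, the 3 members with the most covered window, ranked by signal where equal and with ties of the last added after they had been seen, and up to 3 without a replicated peak in alphabetical order; the genes of the 10 longest domains; the 5 most covered genes of each replicate alone; and the 10 other genes with the highest signal. Names outside this rule are marked as such. Alternatives were windows of 1 and 5 kb, any annotated TSS, at least 50% of the window covered, q under 0.01, each replicate's list alone, the pooled list, a CpG-rich background, 1000 rotations of the gene order, other overlaps, the same number of top peaks, and merge gaps of 1 and 10 kb. Added after the data had been seen were the replicated peaks that met the overlap in both replicates, and genes on chromosomes 1 to 19 alone.

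The overlap step was checked against bedtools 2.31.1 on replicate 1 (82098 of 144335 peaks covered by both methods). On simulated data, with 40.1% of replicate 1 peaks left in place and the rest shifted, 40.9% were recovered. Planted lists of 20 genes, with every member set as marked, were recovered in 100% of cases. That setting largely fixes the outcome, which does not cover partly marked lists. With shifted peaks 5% of the fixed lists fell below p = 0.05 in Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. A single replicate 1 peak outside chromosomes 1 to 19, X and Y was left out of the tests. Signal tracks and alignments were not analysed here.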

Results

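H3K27me3, the trimethylation of lysine 27 on histone H3 that Polycomb repressive complexes deposit at silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at 10.5 days. The hindbrain is the part of the neural tube that forms the medulla, pons and cerebellum. There was 1 group of 2 biological replicates of strain B6NCrl, each a pool of both sexes. Replicate 1 was made from 69 embryos and replicate 2 from 51. The authors' peak lists held 144335 peaks for replicate 1, 121742 for replicate 2, 162179 for the pooled reads and 69689 for the list they named replicated. Read depth is unknown from these lists, so no value below carries a counting interval. Only this tissue, stage and mark were analysed here, and the comparisons are therefore between genes, regions and chromosomes within this tissue, and between the replicates. Coordinates are on mm10.

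The replicates were compared first, to see which part of the map both pools share. Marked sequence overlapped far more than shifted peaks did, and the overlap rose with peak strength. Of replicate 1 peaks, 56.9% had at least 50% of their length inside replicate 2 peaks, against 3.80% after circular shifts (permutation p = 0.0099, the smallest that 100 shifts can give). Of replicate 2 peaks, 28.3% were covered in this way by replicate 1, against 2.47% after shifts (permutation p = 0.0099). When a pair of peaks had to overlap by 50% of both, the shares were 15.2% of replicate 1 and 18.0% of replicate 2 peaks (permutation p = 0.0099 for both). The Jaccard index over base pairs was 44.9% (1.58% after shifts, permutation p = 0.0099), and 44.9 Mb were shared. Among the top 20% of peaks by the authors' p-value, 90.7% of replicate 1 peaks and 64.2% of replicate 2 peaks were covered, against 36.7% and 12.8% of the lowest 20%. Peaks of replicate 2 were wider (median 339 bp against 216 bp) and covered 85.8 Mb against 59.0 Mb. Across the 92775 replicate 1 peaks with an overlapping partner, peak signal correlated with a Spearman rho of 0.43, a value across peaks, which are not independent replicates; it was 0.63 when peaks had to overlap by 50% reciprocally. Both replicates' lists were derived with the same 2 further input files, so their overlap is not wholly independent.

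The replicated peaks were enriched at gene starts and in GC-rich sequence, although intergenic sequence and introns held more of their base pairs than promoters did. Promoters, taken as 2 kb either side of an annotated transcription start site (TSS), held 19.0% of replicated peak base pairs, 5.83-fold the 3.26% of shifted peaks (permutation p = 0.0099). In the replicates' own lists the promoter share was 18.1% ± 0.32 (SD, n = 2). Outside promoters, 5' untranslated regions were 4.20-fold, coding exons 2.32-fold and 3' untranslated regions 1.56-fold over shifted peaks (permutation p = 0.0099 for each). Intergenic sequence was under-represented, with 41.7% of base pairs against 58.6% after shifts (permutation p = 0.0099). The intron share of 34.3% did not pass against 35.6% after shifts (permutation p = 0.129); in replicate 2 alone it was lower, at 0.942 of the shifted share (permutation p = 0.0198). Peaks had a GC content of 49.8%, against 41.8% after shifts, and an observed over expected CpG of 0.278 against 0.191 (permutation p = 0.0099 for both). Of the 10083 protein-coding genes with a CpG-rich promoter, 36.2% carried a replicated peak, against 25.6% of the 11855 others (odds ratio 1.65, Fisher's exact test, two-sided, p = 1.04e-64).

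In all, 6684 of 21938 protein-coding genes (30.5%) had a replicated peak within 2 kb of the TSS and are called marked below. The replicates' own peaks marked 34.4% ± 2.4 of genes (SD, n = 2), and 6596 genes were marked in both. The 6684 genes include 313 with a peak in replicate 2 only and 36 with a peak in replicate 1 only. At 3521 genes peaks covered at least 50% of the 4001 bp window. The lists come from pooled hindbrain tissue, so a call does not show the mark in every cell or silence of the gene. Of the 19 gene lists, 13 were marked more often than the other genes and 1 less often, after Benjamini-Hochberg adjustment over the 19 lists of Fisher's exact test (two-sided).

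**Figure D1:**
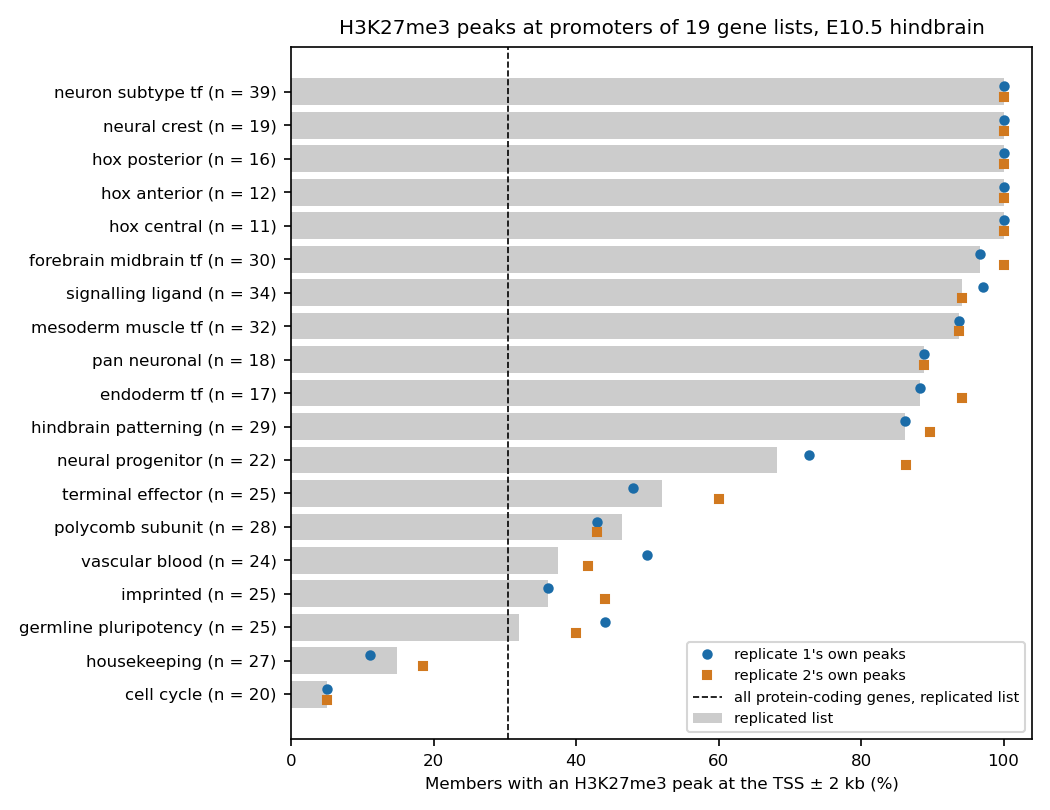
Percentage of the members of each of 19 gene lists (rows, n in brackets) with an H3K27me3 peak within 2 kb of the TSS. Bars show the replicated list, circles replicate 1 and squares replicate 2, each a single list with no error bar, and the dashed line the 30.5% of all protein-coding genes. Transcription factor, Hox and signalling lists lie at 86.2% or above in the replicated list, and the cell cycle list at 5%.

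The Hox genes, which set position along the body axis, were the most uniformly marked group: each of the 39 listed members had its whole TSS window inside a replicated peak. The hindbrain uses the anterior paralogue groups, so the comparison of interest was between these and the posterior groups. All 12 anterior genes (groups 1 to 4), all 11 central genes (groups 5 to 8) and all 16 posterior genes (groups 9 to 13) were marked, in the replicated list and in each replicate (adjusted p = 1.34e-06, 3.61e-06 and 1.48e-08 by Fisher's exact test). Neighbouring Hox genes share peaks and are not independent, so these p-values are too small. With rotations of the gene order in place of Fisher's exact test, the adjusted p was 0.00158 for each of the 3 groups. Anterior and posterior members did not differ (Fisher's exact p = 1), a comparison at its ceiling that a binary call cannot resolve. The smallest window coverage in replicate 1 was 97% among anterior, 94.5% among central and 90.7% among posterior genes, and it was 100% in replicate 2 for all 3 groups. The Hoxa cluster (chromosome 6, 52155590 to 52260880) lay within a single replicated peak of 126 kb, and the Hoxc cluster (chromosome 15, 102921103 to 103036852) within one of 143 kb. Hoxd (chromosome 2, 74668310 to 74765142) was covered over 99.6% of its length by the replicated list and 98.9% ± 0.63 by the replicates (SD, n = 2). Hoxb (chromosome 11, 96194316 to 96368256) was covered over 87.1%, or 84.6% ± 4.0 in the replicates (SD, n = 2), with most of the uncovered sequence between Hoxb13 and Hoxb9. Peak signal, an enrichment value of the authors whose scale is not stated, ran from 13.1 to 24.1 at anterior and from 21.9 to 24.1 at posterior TSSs. By signal, Hoxc4, Hoxd3 and Hoxd4 led the anterior list, Hoxc5, Hoxc6 and Hoxc8 the central list, and Hoxc9, Hoxc10, Hoxc11, Hoxc12 and Hoxc13, which lie in the same peak and are tied, the posterior list. The gene records of Hoxd3 and Hoxd4 begin at almost the same base (74711927 and 74711929), so these genes share a window. The record of Hoxc5 begins at 102967443, beside that of Hoxc10 (102966796), and that of Hoxa3 at 52213336, between Hoxa6 and Hoxa7. The windows of Hoxc5 and Hoxa3 thus lie among genes of other groups.

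**Figure D2:**
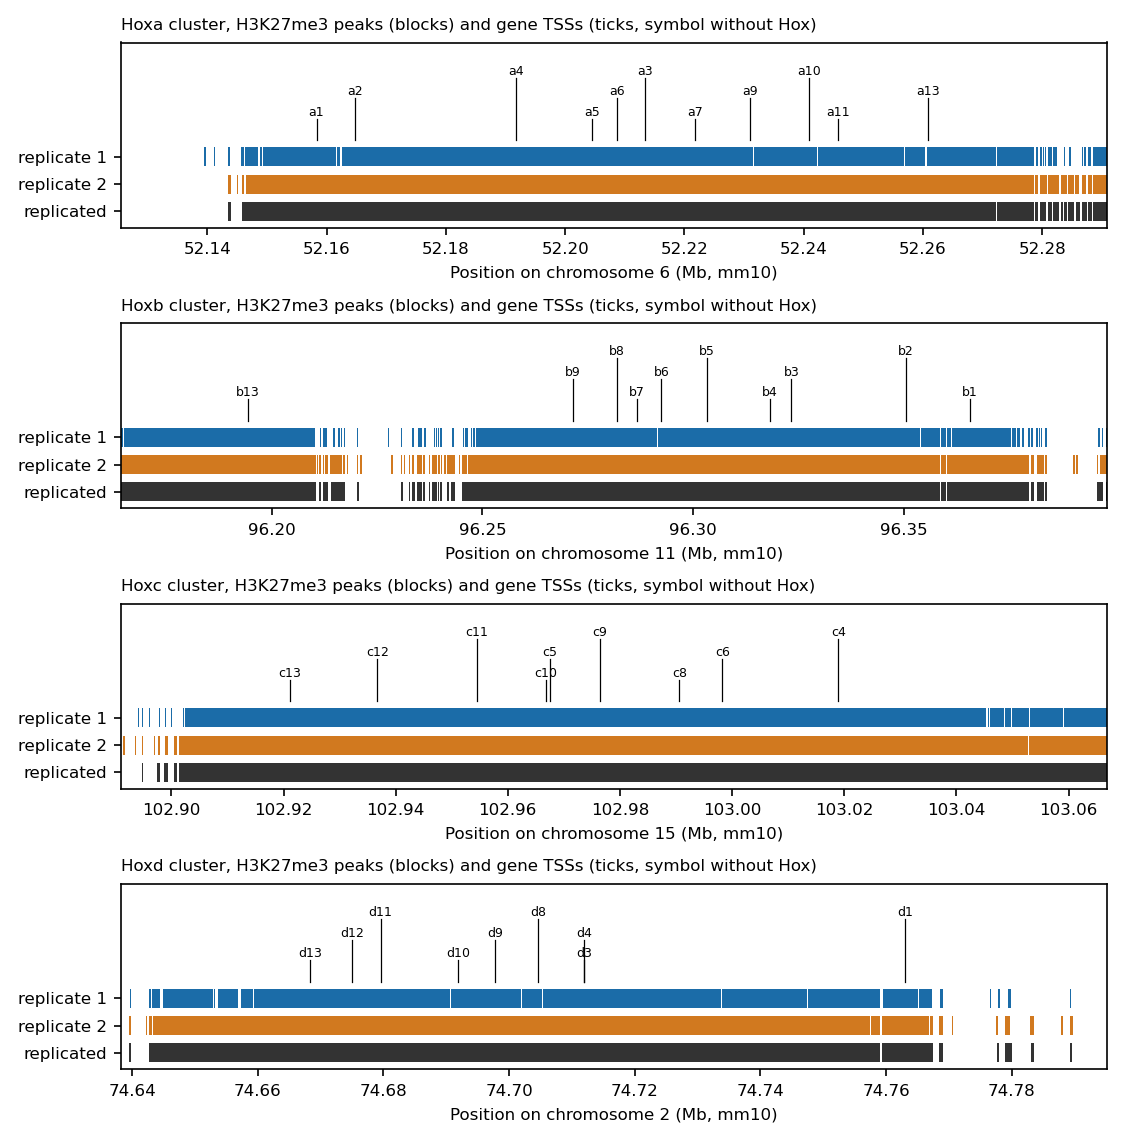
H3K27me3 peaks over the 4 Hox clusters, drawn to scale with 30 kb on either side (horizontal axes, position in Mb on mm10). Blocks are peaks of replicate 1, replicate 2 and the replicated list, and ticks mark gene TSSs; Hoxa and Hoxc each lie within 1 replicated peak, and most of the uncovered part of Hoxb is between Hoxb13 and Hoxb9.

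Regulators of brain regions and of neuron types were marked at nearly every promoter, whether or not they belong to the hindbrain. Of the 29 hindbrain and isthmus patterning genes, 25 (86.2%) were marked (adjusted p = 2.29e-09, Fisher's exact test). Ptf1a, a factor of inhibitory neuron progenitors, was covered over 100% of its window with a peak signal of 29.0, as were Fgf8, the signal of the isthmus (19.6), and Cyp26c1, a retinoic acid-degrading enzyme (18.9). The 4 genes without a replicated peak were the homeodomain cofactors of Hox proteins: Meis1, Meis2, Meis3 and Pbx1, the last named after its value was seen. Peaks of 1 replicate reached a small part of the windows of Meis2 (6.02% covered in replicate 2) and Meis3 (4.67% in replicate 1). Of 30 forebrain and midbrain transcription factors, 29 were marked (adjusted p = 1.38e-13, Fisher's exact test), led by Six3, Gsx1 and Fezf2 with signals of 23.9, 20.7 and 19.8; Hesx1 had only a peak covering 7.07% in replicate 2. All 39 transcription factors of neuron subtypes and their progenitor domains were marked in both replicates (adjusted p = 1.30e-19, Fisher's exact test). Evx2, an interneuron factor next to the Hoxd cluster, had a signal of 23.5. This is the same value as the strongest replicated peak over that cluster, so it may not be a separate measure. Olig1 and Olig2, factors of the oligodendrocyte and motor neuron lineage, had signals of 23.0 and 21.7.

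Neural progenitor markers and pan-neuronal genes were also marked more often than other genes. Of 22 neural progenitor markers, 15 (68.2%) were marked (adjusted p = 4.67e-04, Fisher's exact test), and 79.5% ± 9.6 in the replicates' own lists (SD, n = 2). Pax6 and Pax3, regional factors of the neural tube, were covered over 100% of the window in the replicated list and 98.1% or more on average in the replicates; Sox1 was covered over 89.2% ± 12 in the replicates (SD, n = 2). Cdh2, the neural cadherin, and Fabp7, a radial glia protein, had no peak in either replicate, and Id3 only one covering 9.95% in replicate 2. Of 18 pan-neuronal genes, 16 were marked (adjusted p = 1.01e-06, Fisher's exact test). Crmp1, Ina and Tubb3, which encode cytoskeletal or growth cone proteins of neurons, were covered over 100% of the window, with signals of 15.9, 15.8 and 7.37. Elavl4, a neuronal RNA-binding protein, and Myt1, a zinc finger factor, had no peak in either replicate.

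Regulators of other lineages and secreted signals were marked at most promoters too. The mesoderm, heart and muscle list had 30 of 32 members marked (adjusted p = 3.68e-13, Fisher's exact test), with Foxf1, Nkx2-5 and Foxc2 covered over 100% of their windows at signals of 22.4, 19.7 and 19.2, and with Eya1 and Tbx6 free of peaks in both replicates. Of 17 endoderm regulators, 15 were marked (adjusted p = 2.36e-06, Fisher's exact test). Neurog3, the factor of pancreatic endocrine progenitors, had the highest signal of the replicated list (31.02; TSS at chromosome 10, 62133090), followed in the list by Cdx2 (24.9) and Pdx1 (19.7); Hnf4a and Hnf4g had no replicated peak. All 19 neural crest and mesenchyme genes were marked (adjusted p = 5.82e-10, Fisher's exact test), led by Dlx3, Twist2 and, tied in signal, Dlx4 and Tfap2a. Of 34 signalling ligands, 32 were marked (adjusted p = 7.66e-14, Fisher's exact test), led by Wnt3a, Wnt10a and Gdf7; Bmp5 had no peak and Fgf10 only one covering 5.85% in replicate 1.

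Of the remaining lists, proliferation genes were marked less often than other genes, effector genes of adult tissues more often, and the rest did not pass. Only E2f1 of the 20 proliferation genes was marked, over 8.20% of its window (adjusted p = 0.0185 for fewer marked genes, Fisher's exact test), and Aurkb, Bub1 and Ccna2 were among the 19 without a peak. With at least 50% of the window required to be covered, the count was 0 and the call was lost (adjusted p = 0.0772, Fisher's exact test). Of 27 housekeeping genes, 4 were marked, which did not pass (adjusted p = 0.116, Fisher's exact test); they were Reep5 (52.3% covered), Rab7 (14.4%), Pgk1 on chromosome X (9.35%) and B2m, the last named after its value was seen. Actb, Chmp2a and Eef1a1 had no replicated peak, although replicate 2 alone covered 22.1% of the Actb window. In replicate 1 alone the housekeeping list had 3 marked genes and passed as depleted (adjusted p = 0.0188, Fisher's exact test). Endothelial and blood genes were marked in 9 of 24 cases (adjusted p = 0.551, Fisher's exact test), led by Sox18, Cldn5 and Tal1 with complete coverage; Aif1, Cdh5 and Csf1r had no replicated peak. All 5 members of this list with a CpG-rich promoter were marked, a difference from other CpG-rich promoters (adjusted p = 0.00907, Fisher's exact test). Germline and pluripotency genes were marked in 8 of 25 cases (adjusted p = 0.831, Fisher's exact test), with Pou5f1, Utf1 and Nanog covered over 100%, 100% and 75.1% of the window, and with Asz1 and Dazl free of peaks and Ddx4 covered over 20.0% in replicate 2 only. Effector genes of adult tissues were marked in 13 of 25 cases (adjusted p = 0.0376, Fisher's exact test), a call lost with replicate 1 alone (12 of 25, adjusted p = 0.158) and with at least 50% of the window required (4 of 25, adjusted p = 1). Muscle actin Acta1, myelin gene Mbp and creatine kinase gene Ckm were the most covered members, and Afp, Alb and Aqp4 had none. Polycomb subunits and H3K27 demethylases were marked in 13 of 28 cases (adjusted p = 0.116, Fisher's exact test); Pcgf5, Phf19 and Cbx8 were covered over 97.7%, 97.6% and 73.9% of the window, and Cbx6, Cbx7 and Eed had no replicated peak. Imprinted genes were marked in 9 of 25 cases (adjusted p = 0.551, Fisher's exact test), and all 9 were covered over at least 50% of the window, so that the list passed when that was required (adjusted p = 0.018). Sfmbt2, Phlda2 and Dlk1 led them, and Gab1, Igf2r and Impact had no replicated peak.

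By symbol family, developmental transcription factors, ligands and potassium channels were marked, and odorant and vomeronasal receptor, zinc finger and ribosomal protein families were marked less often than other genes. Among 19 families, 13 were marked more often and 4 less often than other genes (adjusted p of at most 0.0131 for each, Fisher's exact test). Every member was marked among the 9 Pax, 8 Lhx, 6 Irx, 14 Nkx, 6 Dlx and 19 Wnt genes and the 6 genes Six1 to Six6, in both replicates. Of Fox genes 36 of 44, of Sox 15 of 19, of Tbx 11 of 15, of Gata 5 of 6 and of Fgf 17 of 22 were marked; the unmarked Gata member was the blood factor Gata1, and the unmarked Sox genes were Sox4, Sox11, Sox13 and Sox15, all named after their values were seen. The unmarked Tbx genes were Tbx6, Tbx10, Tbx19 and Tbx22, and the unmarked Fgf genes were Fgf6, Fgf7, Fgf10, Fgf12 and Fgf20, again named after their values were seen apart from Tbx6 and Fgf10. Potassium channel subunits, which act in excitable cells, were marked in 76 of 92 cases (82.6%, adjusted p = 3.03e-24, Fisher's exact test). Olfactory receptors were marked in 4 of 1093 cases, vomeronasal receptors in 0 of 327, Zfp zinc finger genes in 44 of 365 and ribosomal protein genes in 6 of 76 (adjusted p = 9.46e-168, 9.71e-52, 3.68e-16 and 9.20e-06, Fisher's exact test). The 4 olfactory receptor genes were Olfr463, Olfr71, Olfr94 and Olfr95, named after their values were seen. In replicate 1 alone 13 olfactory receptor genes were marked and in replicate 2 alone 7, and 11 ribosomal protein genes were marked in replicate 2 alone; both families stayed below other genes in each replicate. Clustered protocadherins (18 of 57) and keratins (12 of 49) did not differ from other genes (adjusted p = 0.886 and 0.462, Fisher's exact test). With the single replicates 20 and 23 keratin genes were marked, a share above rather than below that of other genes that again did not pass (adjusted p = 0.238 and 0.143, Fisher's exact test). Members of a family that sit side by side share peaks and are not independent.

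Outside the lists and families, the strongest promoter peaks lay at Gm49601, Gp1bb and Sept5, neighbours on chromosome 16 (18620317 to 18629954) that share a peak of signal 26.8. Next came the adrenergic receptor gene Adra2c (25.9), the thyroid hormone deiodinase gene Dio3 (25.5), the transcription factor gene Nfix (25.3), Urad beside Cdx2 (24.9), the early response factor gene Egr3 (24.8), Fam43b (23.6) and Gm28230 in the Hoxd cluster (23.5). Peaks covered at least 83.3% of each of these windows.

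Merging replicated peaks across gaps of up to 3 kb gave 21340 domains with a median length of 1924 bp. The 2659 domains of at least 10 kb (12.5%) held 58.4% of the domain sequence. There were 44 domains of at least 100 kb, 17 of them on chromosome X. In replicate 1 alone 28 of 56 such domains were on X, and in replicate 2 alone 16 of 54. The longest, 330 kb on X (99347379 to 99677631), contained the TSS of Pja1, a ubiquitin ligase gene, and was covered by peaks over 86.0% of its length. Of the 10 longest, 7 were on X; the others were the Hoxc domain of 263 kb, the Hoxa domain of 190 kb, which reached the neighbouring Evx1, and a 220 kb domain at Prdm16 on chromosome 4. The other X domains contained the TSSs of Hsd17b10, Ribc1, Smc1a and Iqsec2 (248 kb), Zcchc13 and Slc16a2 (242 kb), Tmsb4x (220 kb), Cdx4, Chic1, Tsx and Gm26992 (175 kb), and Klhl15, Fam90a1b and Apoo (172 kb), and a 235 kb domain lay over part of Nhs. The X domains reached signals between 6.74 and 13.1, against 24.1 in the Hoxc and 21.9 in the Hoxa domain. The number of domains depends on the peak list: it was 37055 with replicate 1 alone and 34050 with replicate 2 alone.

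Chromosome X carried the largest covered share in the replicated list, and the autosomes ranged widely. Peaks covered 5.83% of X against a median of 2.66% over the 19 autosomes, a ratio of 2.19 that placed X first of 20 (exact rank p = 0.05, the smallest this ranking gives). In replicate 1 alone the ratio was 2.45 and X was again first. With replicate 2 alone it was 1.66 and X ranked 3 of 20, behind chromosomes 11 and 19 (exact rank p = 0.15). The rank of X thus rests on replicate 1. X itself was covered over 4.96% in replicate 1 and 5.29% in replicate 2. The autosomal median was 2.03% and 3.18%, so the larger ratio in replicate 1 goes with its lower autosomal coverage. The ratio fell with peak strength. At a −log10 q of 10 or more it was 1.44 in the replicated list (X ranked 3 of 20), 0.528 in replicate 1 and 0.614 in replicate 2 (rank 19 in each). At 20 or more, a bound chosen after the results had been seen, it was 0.495 in the replicated list, the lowest of the 20. Replicated peaks carry values of the pooled list, so 1 bound is not the same strength in each list. The bound of 10 kept 14481 of 69689 replicated peaks, 6077 of 144335 in replicate 1 and 9640 of 121742 in replicate 2. Among autosomes the covered share ran from 1.44% on chromosome 3 to 4.77% on chromosome 11. CpG-rich promoters on X were marked in 119 of 253 cases (47.0%), against 35.9% on the autosomes (odds ratio 1.58, Fisher's exact p = 4.24e-04), and this held in replicate 1 (odds ratio 1.93, p = 3.13e-07 by Fisher's exact test) and in replicate 2 (1.55, p = 7.52e-04 by Fisher's exact test). Other X promoters were marked in 29.4% of cases against 25.8% (odds ratio 1.197, Fisher's exact p = 0.0401), which was not the case with replicate 2 alone (odds ratio 1.03, Fisher's exact p = 0.769). Neighbouring X promoters can share a domain and are not independent, and a single chromosome is compared, so these p-values may be too small. No list held a peak on Y.

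**Figure D3:**
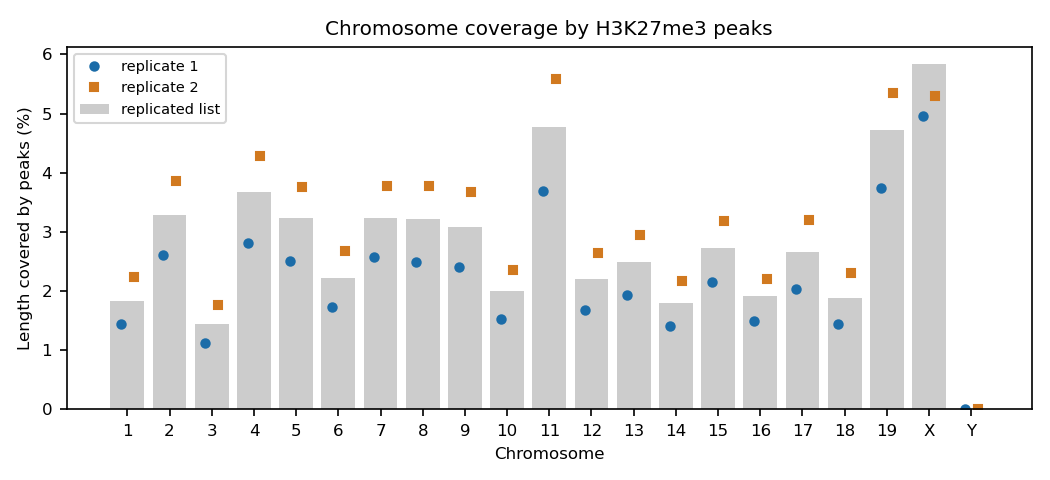
Percentage of each chromosome's length (vertical axis) covered by H3K27me3 peaks, for chromosomes 1 to 19, X and Y (horizontal axis). Bars show the replicated list, circles replicate 1 and squares replicate 2, each a single list with no error bar; X reaches 5.83% in the replicated list, while chromosomes 11 and 19 lie above X in replicate 2.

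Promoters marked in a single replicate had a small share of the window covered, by the median. There were 570 genes with a peak in replicate 1 only and 1320 in replicate 2 only, and peaks covered a median of 4.07% and 8.11% of their windows, against 34.0% at the 6596 genes marked in both. The most covered genes of replicate 1 only were Gm20489, Arl13a, Il12b, Lhfpl1 and Lcn3, with 48.2% to 15.9% of the window covered, and 3 of these (Gm20489, Arl13a and Lhfpl1) are on X. Those of replicate 2 only were Ssbp4, Zcchc12, Grik2, Mppe1 and Sox9, with 68.7% to 51.2%. Each of these, and Gm20489 and Lhfpl1 of replicate 1 only, still had a replicated peak in the window and counts as marked. The same held for 36 of the 570 genes in replicate 1 only and 313 of the 1320 in replicate 2 only (23.7%). Of all 570 genes in replicate 1 only, 52 (9.12%) were on X, against 3.03% in replicate 2 only and 4.81% of the genes marked in both. Of the fixed lists, the neural progenitor and adult effector lists each had 3 genes in replicate 2 only. With 1 list per replicate, these counts describe the 2 libraries and carry no test.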

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

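Each result below was repeated under its own set of alternatives: the CpG-rich background and the rotations cover the gene lists alone, the X promoter odds ratios were repeated in the single replicates alone, and the lncRNA tests were not repeated. The set of peaks that met the overlap in both replicates and the restriction to chromosomes 1 to 19 were chosen after the data had been seen. Of 492 values under alternatives for 58 results, 452 kept their direction and their side of the threshold, or their size. No paired analysis was possible because the design has 1 group only. Unless the construction of an alternative shows it, the cause of a change was not tested. In the 19 families, 13 calls above and 4 below other genes were counted under each of the 11 settings; the enriched lists numbered 12 or 13.

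Adult effector genes lost their call with the 1 kb window (44.0%), at least 50% of the window covered (16%), the pooled peaks (56.0%), the peaks with the overlap in both replicates (48.0%), autosomes alone (50%) and CpG-rich promoters alone (100%, a single gene); they were at 48.0% and 60.0% in the single replicates. The cell cycle list lost its call at 50% coverage (0%). The housekeeping list became depleted with the 1 kb window (7.41%) and was at 11.1% and 18.5% in the single replicates. Among CpG-rich promoters alone the endothelial and blood list became enriched (100%), and at 50% coverage the imprinted list did (36.0%). Lists and families that did not differ from other genes changed side without passing: germline genes with the 1 kb (24.0%) and 5 kb windows (32.0%), any TSS (32.0%) and CpG-rich promoters (21.4%); imprinted genes among CpG-rich promoters (18.2%); protocadherins with any TSS (31.6%) and the single replicates (29.8% to 35.1%); keratins with the 5 kb window (38.8%), the pooled peaks (46.9%) and the single replicates (40.8% to 46.9%).

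The intron share over shifted peaks was 0.942 to 0.986 in the single replicates, and the X ratio 1.66 to 2.45. Domain numbers follow the merge gap by construction: 33206 at 1 kb and 14117 at 10 kb, and 34050 to 37055 in the single replicates. Domains of at least 10 kb fell to 1527 at 1 kb; those of at least 100 kb numbered 10 at 1 kb and 147 at 10 kb. The longest measured 172 kb at 1 kb, 868 kb at 10 kb, 366 to 407 kb in the single replicates and 263 kb, then at Hoxc, for peaks with the overlap in both replicates. Spearman's rho was 0.63 for reciprocal overlap. With the same number of top peaks, 323 genes were marked in replicate 1 only. Unknown read depth limits what the absence of a peak can show at a weakly marked promoter.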

Other observations

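Long non-coding RNA (lncRNA) genes at developmental genes were marked more often than other lncRNA genes. All 15 annotated members of a list of antisense or bidirectional transcripts at developmental genes were marked, against 21.4% of other lncRNA genes (adjusted p = 2.87e-10 over 3 lists, Fisher's exact test). Hotair, the Hoxc antisense transcript, Hottip at the end of Hoxa and Six3os1 were covered over 100% of the TSS window in both replicates, with signals of 24.1, 21.9 and 23.9; Sox2ot, which runs across Sox2, was covered over 22.1%. Many of these share a peak with their coding neighbour: 36.7% of the 2946 lncRNA genes within 10 kb of a coding TSS were marked, against 15.3% of the 7209 farther away. None of 9 abundant lncRNA genes, Malat1 and Neat1 among them, was marked, which did not pass (adjusted p = 0.22, Fisher's exact test). Of 7 imprinted or X-linked ones, H19, Meg3, Tsix and Ftx were marked and Xist, Jpx and Kcnq1ot1 were not (adjusted p = 0.0643, Fisher's exact test). The lncRNA lists were written before their values were seen.

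The tests on sequence outside repeats, on peaks with −log10 q below 5, on CpG-rich escape genes, on other numbers of top peaks and on CpG content were chosen after the results had been seen; the bounds of the others were written beforehand.

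Chromosome X carried 2.19 times the median autosomal coverage, with a jackknife SE of 0.63 over 35 blocks of 5 Mb. Reads from repeats are argued against: the repeat share of peaks over that of the chromosome differed by −0.0277 (X minus autosomes; −0.0165 ± 0.023 in the replicates, SD, n = 2), and over bases outside repeats the X ratio was 2.66. Without peaks of −log10 q below 5 the ratio in the replicated list was 2.15 ± 0.63 (jackknife SE over blocks of X alone). This lies above a bound of 1.2 by more than 1 SE, too small a margin to exclude such peaks as the whole cause. In the single replicates they stay open too, with 1.62 ± 0.47 and 1.22 ± 0.34, too uncertain to place against that bound. The cut kept 42091 replicated peaks, 21701 of replicate 1 and 26909 of replicate 2, so the lists were not held to equal strength. Weak peaks up to a higher bound also stay open: at 10 or more the ratio was 1.44 ± 0.41 in the replicated list, 0.528 in replicate 1 and 0.614 in replicate 2, and at 20 or more it was 0.495 in the replicated list, the lowest of the 20 chromosomes. An inactive X in the female cells stays open as a hypothesis. Of escape genes with CpG-rich promoters 0 of 5 were marked (1 of 5 in each replicate). Among other X genes with such promoters 119 of 248 were marked (Fisher's exact p = 0.0622). With Mid1, which is marked but not CpG-rich, the escape genes had 1 of 6 marked (Fisher's exact p = 0.217). So few genes cannot settle these differences. Nor were the escape genes matched to the other X genes for expression, which peak lists do not measure.

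Replicate 1 had 17.0% of its peaks on X and replicate 2 had 13.4%. A longer tail of weak peaks in replicate 1 is argued against. With 69689 top peaks from each the shares were 20.7% and 13.3%, a ratio of 1.56. With 5000 to 40000 from each the ratio was 1.30 to 1.95, highest at 5000. With 2000 from each it was 1.08, with 0.65% and 0.6% on X, so the excess is not seen there. At a −log10 q of 10 or more the shares were 5.17% of 6077 peaks and 5.96% of 9640, unlike numbers of peaks that do not compare equal ranks. By length, X was covered less in replicate 1 (4.96%) than in replicate 2 (5.29%). The autosomal median was 2.03% against 3.18%, so by length the excess in replicate 1 is relative to the autosomes. A different female share or state of X between the pools remains a candidate for the larger X share of replicate 1. At shared peaks, each replicate 1 peak was set against the strongest replicate 2 peak that overlapped it. The median log2 signal ratio of replicate 1 over replicate 2 was 0.17 on X and −0.23 to −0.10 on the autosomes. X thus stood 0.27 above the highest autosome. X was above each autosome in the top 25% (−0.37 against −0.73 at most) and in the lower 50% (0.28 against 0.16 at most) of peaks by replicate 2 signal. The ratio changed with strength: the autosomal median was −0.77 in the top 25% and 0.15 in the lower 50%. X held 3.44% of replicated peaks at a −log10 q of 20 or more, against 17.4% of all. A difference in peak strength or width between X and the autosomes may therefore not be fully removed by these strata. The sex ratio of the pools was not measured, and a difference between libraries in how X was recovered would look alike.

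Of the replicated peaks, 13550 (19.4%) did not overlap peaks of both replicates by 50% of either peak. The test of narrow calls in 1 replicate set against a wide one in the other could not decide. A narrow call inside a wide peak meets the overlap by its own length, so few such peaks could be among the 13550. Peaks of both replicates touched 4.10% of the 13550, and 99.0% of all replicated peaks touched by both met the overlap. Peaks too weak to be called in 1 replicate remain a candidate explanation: the median −log10 q of the 13550 was 4.12, below the lower quartile of the other replicated peaks (4.61). Replicate 2 alone touched 68.0% of them and replicate 1 alone 25.8%. The design gives no biological explanation to test here.

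Promoter CpG content was tested as a hypothesis for which genes of other tissues were marked. Over the endothelial and blood, germline and adult effector lists together, 9 of 20 CpG-rich and 21 of 54 other promoters were marked, which leaves it open (Fisher's exact p = 0.79). By list, the counts were 5 of 5 against 4 of 19 for endothelial and blood genes (Fisher's exact p = 0.00296), 3 of 14 against 5 of 11 for germline genes (Fisher's exact p = 0.389) and 1 of 1 against 12 of 24 for adult effector genes (Fisher's exact p = 1). No test compared the lists with each other.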
